A study of Mus musculus with 12 samples.

How the data were processed

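Total RNA of 2 mouse bone cell lines was measured on 12 one-colour spotted arrays, 3 for each of 4 groups. The line 2T3 is an osteoblast line and MLO-Y4 an osteocyte line, each from a mouse carrying T antigen behind a bone-cell promoter, per the labels. The 2T3 groups are called C0 and low, and the MLO-Y4 groups high and low. Per the labels, the 2T3 groups contrast sparse with confluent osteoblasts and the MLO-Y4 groups contrast osteocytes that have gap junctions with osteocytes that lack them. C0 was read as the confluent state only because the other 2T3 group is called low, and high was read as the group with gap junctions for the same reason. The labels number the arrays 1 to 3 in each group but do not say whether a number marks a separate culture, so the p-values measure only the spread between these arrays, which may be technical.

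The deposited values are linear spot intensities, whole numbers from -23 to 53055, read as intensity from the values themselves. Values below 0 show that a background had been subtracted. The image software, the background method and any rejected spots are not given in the sources used here, and no normalization between arrays was visible in the deposited intensities. Median intensity per array ran from 4 to 55, mean intensity from 42.2 (2T3 low replicate 3) to 334 (2T3 C0 replicate 3) and total intensity from 212491 to 1680311. Each array held 5030 spots. A platform annotation table listed 4638 of them, 4633 with 1 gene symbol and 5 with several, and 392 were unnamed here. Symbols were updated through Entrez identifiers for 4624 spots and kept as given for 9, which left 4606 distinct genes. No spot with several symbols was named.

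Arrays were scaled to equal medians, values were floored and log2 was taken. The rule fixed before the data were examined set the floor at the 10th percentile of all scaled values, but that percentile was -1.32 and has no logarithm. The 25th percentile, 3.96 scaled units, which had been planned as an alternative, was used in its place. Values at the floor have no order. Each array's detection limit was taken as the size of its lowest value, a rule chosen after the data were examined. By that rule 1253 spots were above the limit on all 12 arrays and 281 on none, and between 37.9% and 74.8% of spots were above it on a single array. A spot below the limit on every array of a group has only a bound there, and its fold is given as at least the brighter group's mean over the mean of the dimmer group's limits, or of its own values where these were higher.

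Differences were tested with limma 3.58.1 in R 4.3.3. lmFit estimated 4 group means over all 12 arrays, with 8 residual degrees of freedom, and eBayes gave two-sided moderated tests. The 6 comparisons were C0 against low in 2T3, high against low in MLO-Y4, MLO-Y4 against 2T3 over both densities, MLO-Y4 low against 2T3 low, MLO-Y4 high against 2T3 C0, and the difference between the 2 density effects. P-values were adjusted over the 5030 spots by Benjamini-Hochberg within a comparison, with a threshold of 0.05, and adjusted p below means this value from limma. Log2 differences are given with the standard error of the fit (SE), and group levels as geometric means of scaled intensity. The number of arrays limits the precision of every value.

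Gene lists were fixed before the data were examined. There were 29 lists with 776 distinct symbols, of which 504 were measured. They covered osteoblast, osteocyte, chondrocyte, adipocyte, fibroblast, endothelial, muscle and macrophage or osteoclast markers, and pathways of matrix, adhesion, growth factors, cytokines, interferon, cell cycle, stress, metabolism and translation. The 28 lists with at least 5 measured genes were tested with camera in limma at a preset correlation of 0.01 on values averaged per gene, with adjustment over the lists of a comparison. Camera compares a list with the other genes. It was repeated with a correlation estimated per list, which raises p where members vary together, and fry was run beside it. Fry's p tests whether a list's genes move, on balance, 1 way and does not compare a list with other genes. The gap junction list had 3 measured genes and was not tested.

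Genes were named by a rule fixed before the data were examined. For the first 3 comparisons it took, among spots with 1 ordinary gene symbol that passed the threshold without overlap between the arrays compared, the 10 largest rises and 10 largest falls, or, where none passed, the spots with the 3 smallest p-values in each direction. It added up to 4 members of each list with the smallest p. For the other comparisons it took the 5 largest rises and 5 largest falls. Pdpn, Phex, Alpl, Bglap and Ibsp were always given. Gja1, Dmp1, Mepe, Sost, Col1a1, Spp1 and Runx2, also in that rule, were not analysed here.

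Same-numbered arrays were checked for pairing by the correlation, across spots, of their deviations from the group means. In MLO-Y4 low and high it was 0.750, 0.607 and 0.708 for numbers 1, 2 and 3, and the arrays of MLO-Y4 high and 2T3 C0 gave 0.654, 0.455 and 0.481, so these numbers were taken to pair the arrays. For 2T3 C0 and 2T3 low it was 0.028, 0.082 and 0.212, and for 2T3 low and MLO-Y4 low 0.0021, -0.126 and 0.213, which did not meet the rule of over 0.1 in every pair. The pairing comes from the data and not from a label. The fit with the number as a block has 6 residual degrees of freedom and treats all groups as paired, 2T3 low included.

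The fit was checked on simulated data with 200 of 5030 spots changed, taken only from spots with a mean level above the median. Values were drawn independently from a normal distribution with each spot's spread in the fit. Deviations shared by same-numbered arrays and differences in scaling between arrays were not simulated, so the shares may be too favourable for the real arrays. For MLO-Y4 against 2T3, 38% of spots changed by 2 on the log2 scale were recovered, 82% of those changed by 3, 88% of those changed by 4 and 0% of those changed by 1, and 7.14% of 112 calls were false. For 2T3 C0 against low the recovered shares were 8%, 32%, 62% and 0%, and 3.77% of 53 calls were false.

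Alternatives planned before the data were examined were quantile normalization, centring on the median log2 value, leaving out the dimmest 25% of spots, a floor at the lowest positive value, a trended robust eBayes, only the arrays compared, array weights, the replicate block, spots averaged per gene, a fold of at least 2, the estimated correlation, fry and leaving out each array. Added after the data were examined were scaling on the spots above the limit on all arrays (detected-spot scaling), upper-quartile scaling, a floor at the median, leaving out the 4 arrays numbered 1, detected-spot scaling with the block, the correlation estimated with the block and removal of a smooth trend over the array surface. The place of each spot on that surface was assumed from its name. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.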

Results

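Gene expression in the osteoblast line 2T3 and the osteocyte line MLO-Y4 was compared across lines and across culture densities, with 3 arrays for each of 2T3 C0, 2T3 low, MLO-Y4 low and MLO-Y4 high. Osteoblasts make bone matrix, and osteocytes are the cells buried in it, which contact each other through long processes and gap junctions. The first principal component held 52.9% of the variance and parted the lines, with all 6 2T3 arrays below 0 and all 6 MLO-Y4 arrays above it. The second held 17.8%. The first also parted arrays within a line. On it, MLO-Y4 low and high replicate 1 lay at 50.5 and 52.3 and the other MLO-Y4 arrays from 5.88 to 15.7. The nearest 2T3 array, C0 replicate 1, lay at -5.16. Components were taken only on values scaled to equal medians. By Spearman correlation, each MLO-Y4 array was closest to the array with the same number at the other density (0.795, 0.898 and 0.863 for numbers 1, 2 and 3).

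The comparison of the osteocyte line with the osteoblast line asked which genes set the lines apart at either density. Each cell type was represented by 1 line. A difference of cell type therefore cannot be told apart from one of the line or its source mouse. Saa3 had the largest difference. This gene, which encodes an acute-phase serum amyloid protein, rose by 12.30 on the log2 scale (SE 0.47, adjusted p = 2.14e-07), from a mean scaled intensity of 5.77 in the 6 2T3 arrays to 29172 in the 6 MLO-Y4 arrays, 5059-fold. In 2T3 it was above the limit on 1 of 6 arrays, so the size of the fold rests on values near the floor. The same holds for Ccl7, also above the limit on 1 of 6 2T3 arrays. The chemokine gene Ccl7 was 562-fold higher in MLO-Y4 (log2 9.14, SE 0.50), the prostaglandin synthase gene Ptgs2 179-fold (7.49, SE 0.66), and the monocyte chemokine gene Ccl2 98.6-fold (6.62, SE 0.49). In the other direction Sfrp2, a secreted modulator of Wnt signalling, fell by 7.30 on the log2 scale in MLO-Y4 (SE 0.46, adjusted p = 9.81e-06), from 1175 to 7.45.

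Lgals3bp, a secreted galectin ligand, rose 126-fold, the adenosine monophosphate deaminase gene Ampd3 115-fold, the BMP antagonist gene Grem1 83.5-fold and Adam23 74.5-fold. Hp, which encodes the haemoglobin-binding protein haptoglobin, was at least 60.7-fold higher and the interferon-induced GTPase gene Gbp2 at least 47.8-fold higher, since neither was above the limit on any 2T3 array. Among the 10 largest falls without overlap between the arrays of the lines were Fscn1, whose product bundles actin (log2 -4.76, SE 0.67, 27.1-fold), the homeobox gene Six2 (-4.62, SE 0.39, 24.5-fold), Mag (-4.31, SE 0.76), the microfibril gene Mfap5 (-4.06, SE 0.73) and Dbp, a clock-controlled transcription factor (-3.98, SE 0.44). Evl (-3.88), the glypican gene Gpc6 (-3.41), Tmsb4x, which encodes an actin-sequestering thymosin (-3.36), and Zfp57 (-3.29) followed. Sfrp2, Fscn1, Dbp and Gpc6 were above the limit on 1 of 6 MLO-Y4 arrays and Mfap5 and Zfp57 on 2 of 6, as was Adam23 on 2 of 6 2T3 arrays, so their folds and order rest partly on background. The falls of Dbp and Gpc6 leaned on 2T3 C0. On the log2 scale Dbp lay from 7.20 to 8.94 in 2T3 C0 and from 4.77 to 5.70 in 2T3 low. Gpc6 lay from 6.26 to 8.35 and from 5.28 to 5.38. Without 2T3 low replicate 1 the fold of Ptgs2 was 114, and without 2T3 C0 replicate 1 that of Grem1 was 54.6. These 20 genes were chosen for passing the threshold without overlap between the 6 arrays of each line, so neither trait is separate evidence. Their adjusted p ran from 2.14e-07 (Saa3) to 0.00496 (Mfap5) in limma. Most 2T3 values of Saa3 and Gbp2 lay at the floor, which narrows their spread and can lower p. Each of the 20 also passed with quantile normalization, detected-spot scaling and the replicate block.

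**Figure D1:**
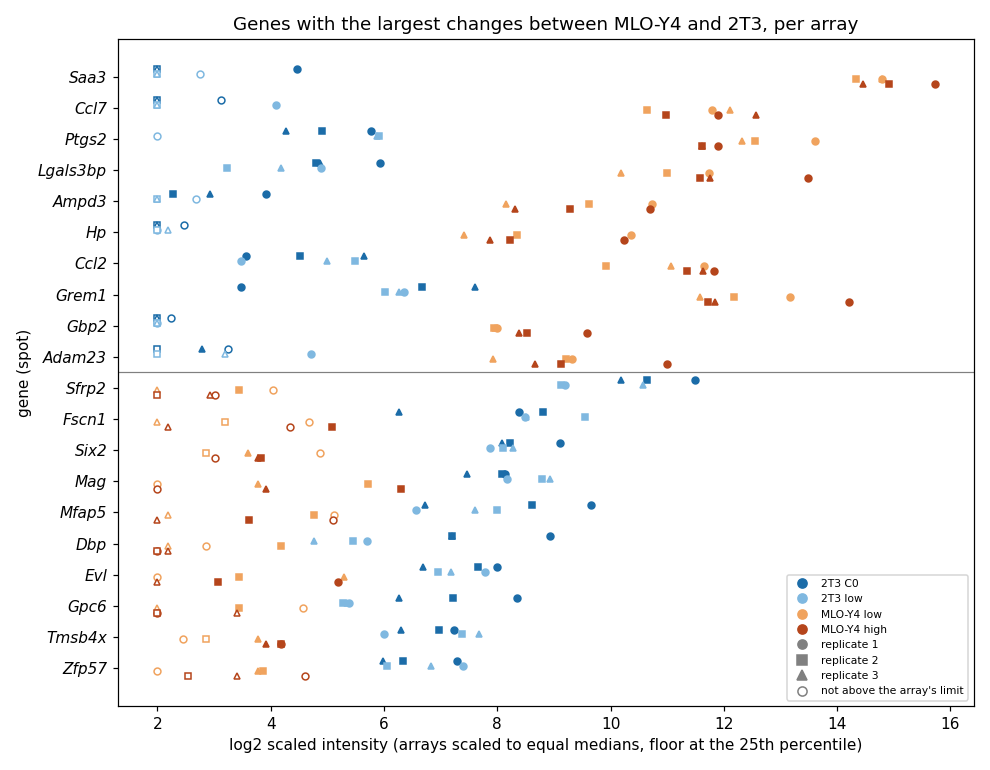
Log2 scaled intensity (horizontal axis) on each of the 12 arrays for the 10 largest rises and 10 largest falls in MLO-Y4 against 2T3 among called genes whose arrays did not overlap between lines, coloured by group, with a symbol per replicate number and open symbols where a spot was not above its array's detection limit. Saa3 lies at a mean of 14.83 in MLO-Y4 and 2.53 in 2T3, and Sfrp2 was above the limit on 1 of 6 MLO-Y4 arrays and 6 of 6 2T3 arrays.

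In all, 508 of 5030 spots passed adjusted p 0.05 in limma, 414 higher and 94 lower in MLO-Y4, and 1081 had an unadjusted p under 0.05 where 251.5 are expected by chance. The balance of directions depended on the scaling. With equal array medians, spots above the limit on all arrays were shifted by a median of 0.79 towards MLO-Y4, against 0.04 with quantile normalization and -0.07 with detected-spot scaling. Control genes printed as triplets were all higher in MLO-Y4 with equal medians. They were Gapdh (2.35), Hprt (0.91), Ywhaz (0.82), Rps29 (0.39), Sdf4 (0.37) and Actb (0.29), each the mean of its spots. The share of calls that were higher was 81.5% with equal medians, 62.6% with quantile normalization (289 higher, 173 lower) and 43.8% with detected-spot scaling (240 higher, 308 lower). Under all 3 scalings 321 spots were called in the same direction, 228 higher and 93 lower. The median intensities of MLO-Y4 low and high replicate 1 were 10 and 9, with lowest values of -20 and -17. Background readings therefore set the scale of these arrays. Folds of named genes are given with equal medians, so rises may be smaller and falls larger with detected-spot scaling.

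Cytokine and resorption genes moved up as a list. Of 19 measured members of the list, 10 were higher and 1 lower in MLO-Y4 (12 and 1 adjusted over the list alone), with a median of 2.65 and camera adjusted p = 3.06e-06. This call held with an estimated correlation (adjusted p = 0.0159). Besides Saa3, Ccl7 and Ccl2, its member with the smallest p was the neutrophil chemokine gene Cxcl5 (log2 4.51, SE 0.35, 22.8-fold). Ptgs2, whose larger rise is given above, is also a member. The chemokine gene Cxcl12, named after its value was seen, was the member that fell (-3.56). Interferon-induced and antigen-presentation genes rose in 14 of 23 cases and fell in 0 (15 and 0 adjusted over the list alone; median 2.29 and 1.49 with detected-spot scaling; camera adjusted p = 4.82e-10, and adjusted p = 0.0510 with an estimated correlation). Usp18, which removes the ubiquitin-like protein Isg15 from its targets, was at least 25-fold higher, the antiviral gene Ifit3 at least 23.8-fold and the transcription factor gene Irf7 at least 22.1-fold, with no 2T3 array above the limit for any of them. Macrophage and osteoclast markers did not move with these lists: 0 of 14 were higher (1 adjusted over the list alone) and 1, Tyrobp, was lower (log2 -3.03, SE 0.63, adjusted p = 0.0110).

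Osteocyte markers were higher in MLO-Y4 in 5 of 9 measured cases and lower in 0 (6 and 0 adjusted over the list alone; median 2.37 and 1.52 with detected-spot scaling; camera adjusted p = 5.09e-04, and adjusted p = 0.248 with an estimated correlation). Pdpn, which encodes podoplanin, a protein of early osteocyte processes, rose by 3.46 on the log2 scale (SE 0.70, adjusted p = 0.00984), from 132 to 1454. Its call was lost without the 4 arrays numbered 1. The chemokine-scavenging receptor gene Ackr3 rose 34.4-fold (5.11, SE 0.38), the actin-severing destrin gene Dstn by 3.45 on the log2 scale (SE 0.43) and the hyaluronan receptor gene Cd44 8.89-fold (3.15, SE 0.69). Phex, a phosphate-regulating endopeptidase gene, was above the limit on 0 of 12 arrays. Dmp1, Mepe, Sost and Gja1 of this list were not analysed here. Dstn and Capg, which also rose, belong to the actin list too, and Cd44 to the focal adhesion list. The rise of the osteocyte list therefore does not by itself establish osteocyte identity. Osteoblast markers split, with 2 of 12 higher and 1 lower (2 and 3 adjusted over the list alone; median -0.44, or -0.0050 with members at their bound; camera adjusted p = 0.224). Dlx3 rose (3.38, SE 0.73, adjusted p = 0.0134) and Msx2 fell (-3.03, SE 0.76, adjusted p = 0.0290), both homeobox genes of osteoblast differentiation. Alpl, the alkaline phosphatase of mineralising cells, rose 7.22-fold (2.85, SE 0.76, adjusted p = 0.0389), and the call ended with quantile normalization (0.105) and detected-spot scaling (0.108), as did that of Dlx3 (0.0935 and 0.0713). Without 1 array, Msx2 was lost in 8 of 12 fits and Alpl in 9. The osteocalcin gene Bglap was at -1.61 (SE 1.04, adjusted p = 0.441), the bone sialoprotein gene Ibsp at -0.44 (SE 0.68, adjusted p = 0.789) and the bone matrix proteoglycan gene Omd at -1.18 (SE 0.40, adjusted p = 0.0955).

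Growth factor genes of the FGF, IGF and PDGF list rose in 7 of 24 cases and fell in 0 (12 and 0 adjusted over the list alone; median 1.20, or 1.03 with members below the limit at their bound, and 0.45 with detected-spot scaling; camera adjusted p = 3.81e-04, and adjusted p = 0.0510 with an estimated correlation). The angiogenic factor gene Vegfa rose 26.2-fold (log2 4.71, SE 0.44), Pdgfa 12.1-fold (3.60, SE 0.30), the receptor gene Egfr 11.6-fold (3.53, SE 0.61) and Fgf7 8.61-fold (3.11, SE 0.56). In the BMP and TGF-beta list 9 of 36 rose and 0 fell (10 and 0 adjusted over the list alone; median 0.80, 0.53 without 2T3 C0 replicate 3 and 0.01 with detected-spot scaling; camera adjusted p = 0.00756, and adjusted p = 0.286 with an estimated correlation), led after Grem1 by the co-receptor gene Eng (5.73, SE 0.60), the activin subunit gene Inhba (4.21, SE 0.53) and Tgfbr3 (3.39, SE 0.49). With the surface trend removed the median of the BMP and TGF-beta list was -0.18, while camera still called it (adjusted p = 7.69e-04). Focal adhesion and integrin genes were higher in 7 of 23 cases and lower in 0 (13 and 1 adjusted over the list alone; median 1.33 and 0.47 with detected-spot scaling; camera adjusted p = 4.29e-04, and adjusted p = 0.358 with an estimated correlation), among them the fibronectin receptor subunit Itga5 (3.68, SE 0.58), the syndecan genes Sdc1 (3.41, SE 0.59) and Sdc4 (2.95, SE 0.50), and Zyx (3.08, SE 0.62). The Wnt list moved down, with 0 of 22 higher and 3 lower (the same counts adjusted over the list alone; median -0.21, or -0.0065 with members at their bound, and -0.78 with detected-spot scaling; camera adjusted p = 0.00756, and adjusted p = 0.259 with an estimated correlation). After Sfrp2 these were the inhibitor gene Dkk2 (-2.27, SE 0.48) and the ligand gene Wnt10b, at least 1.85-fold lower. The call held in all 12 fits without 1 array, while the median ran from -0.38 to -0.0066.

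Genes that hold the cell cycle or answer to p53 rose in 4 of 18 cases and fell in 0 (7 and 1 adjusted over the list alone; median 0.87, 1.35 without MLO-Y4 high replicate 2 and 0.059 with detected-spot scaling; camera adjusted p = 0.00658, and adjusted p = 0.564 with an estimated correlation). These were the kinase inhibitor gene Cdkn1a (log2 5.19, SE 0.53, 36.6-fold), Gas2 (5.02, SE 0.51), Mdm2, the ubiquitin ligase of p53 (4.07, SE 0.37), and the tumour suppressor gene Cdkn2a (2.30, SE 0.47). The cell cycle and DNA replication list was lower, with 2 of 46 higher and 5 lower (4 and 9 adjusted over the list alone; median -0.45, or -0.21 with members at their bound, and -1.27 with detected-spot scaling; camera adjusted p = 0.0136, and adjusted p = 0.623 with an estimated correlation). The cyclin gene Ccnd2 (3.32, SE 0.55) and the ribonucleotide reductase gene Rrm2 (2.37, SE 0.55) rose, and the histone chaperone gene Nasp (-1.56, SE 0.39) and the mitotic kinesin gene Kif20a (-2.54, SE 0.65) fell. The call of this list ended without 2T3 C0 replicate 1 (adjusted p = 0.0514) and without 2T3 low replicate 2 (0.0657), and its median was -0.17 without MLO-Y4 low replicate 3. Antioxidant and detoxification genes rose in 9 of 27 cases and fell in 0 (12 and 0 adjusted over the list alone; median 1.10 and 0.35 with detected-spot scaling; camera adjusted p = 4.29e-04, and adjusted p = 0.358 with an estimated correlation), including haem oxygenase Hmox1 (4.24, SE 0.39), Aldh3a1 (4.10, SE 0.44), the metallothionein gene Mt1 (3.61, SE 0.39) and Gstt1 (3.46, SE 0.50). Glycolysis and hypoxia genes rose in 5 of 19 cases and fell in 0 (5 and 0 adjusted over the list alone; median 1.04 and 0.26 with detected-spot scaling; camera adjusted p = 0.00262, and adjusted p = 0.286 with an estimated correlation), with Vegfa, the vasodilator peptide gene Adm (3.80, SE 0.54), and Gapdh (2.80, SE 0.46, the spot with the smallest p, and 2.35 as the mean of its spots) and Aldoa (2.25, SE 0.41) of glycolysis. The call of Rrm2 ended with quantile normalization (limma adjusted p just over 0.05), and without 1 array Nasp was lost in 7 of 12 fits and Kif20a in 8.

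Heat shock and endoplasmic reticulum stress genes were higher in 2 of 15 cases and lower in 0 (4 and 1 adjusted over the list alone; median 0.94 and 0.23 with detected-spot scaling; camera adjusted p = 0.0483, and adjusted p = 0.617 with an estimated correlation), and this call ended with quantile normalization (0.495), detected-spot scaling (0.207) and in 7 of 12 fits without 1 array. The 2 were Ddit3 (log2 3.46, SE 0.63), a stress-induced transcription factor, and Hspb1 (1.83, SE 0.49). With detected-spot scaling neither passed (adjusted p = 0.0663 and 0.110), and Hspb1 was lost in 9 of 12 fits without 1 array. Adipocyte markers were lower in 1 of 6 cases, Pparg (-2.38, SE 0.60; lost in 9 of 12 fits without 1 array), and higher in 0 (the same adjusted over the list alone; median -0.89, or -0.78 with members at their bound; camera adjusted p = 0.0485, and adjusted p = 0.433 with an estimated correlation). That call ended with the replicate block (0.0691), quantile normalization (0.0906), detected-spot scaling (0.183) and in 8 of 12 fits without 1 array. Camera called 13 of 28 lists between the lines, fry 11, and 1, the cytokine list, held with an estimated correlation. With the correlation estimated in the fit with the replicate block, 3 held, the cytokine, interferon and FGF, IGF and PDGF lists (camera adjusted p = 0.0467 each).

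**Figure D2:**
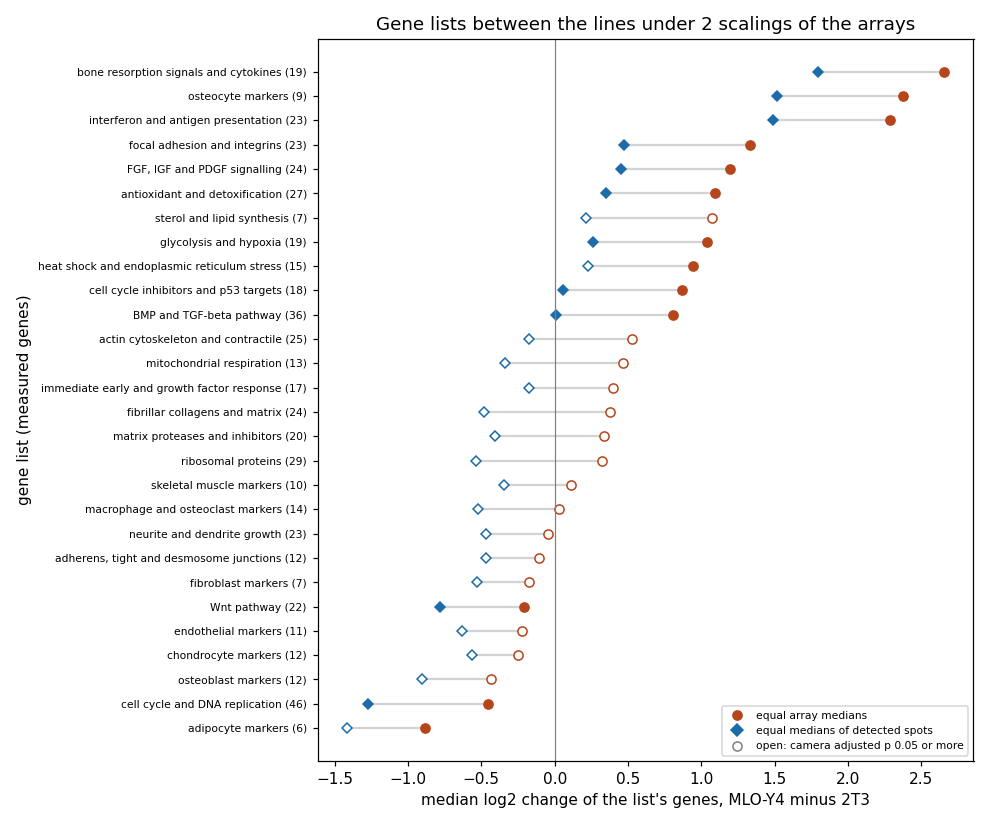
Median log2 difference between MLO-Y4 and 2T3 (horizontal axis) of the measured genes of 28 gene lists, with arrays scaled to equal medians (circles) or to equal medians of detected spots (diamonds), filled where camera's adjusted p was under 0.05. The cytokine list had the highest median under both, 2.65 and 1.80, and the adipocyte list the lowest, -0.89 and -1.41.

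The same lines were then compared at matched density, on different arrays for each density. At low density Saa3 was at least 3152-fold higher in MLO-Y4, Ccl7 was 451-fold higher (log2 8.82, SE 0.71), Ptgs2 302-fold (8.24, SE 0.93), Ampd3 at least 89.5-fold and Lgals3bp 117-fold. Sfrp2 fell by 6.47 on the log2 scale (SE 0.65), Fscn1 was at least 30.3-fold lower, Mag fell by 4.81 and Six2 fell by 4.30, and Tyrobp was at least 8.54-fold lower. At the denser state Saa3 was 4750-fold higher in MLO-Y4 high than in 2T3 C0 (12.21, SE 0.67), Ccl7 at least 587-fold, the ubiquitin-like interferon product Isg15 149-fold (7.22, SE 0.92), Lgals3bp 135-fold and Ccl2 130-fold. Sfrp2 was at least 125-fold lower, Dbp at least 15.8-fold, Gpc6 at least 11.1-fold, Six2 fell by 4.93 and Mfap5 fell by 4.76 (27.0-fold, and 47.3-fold without 2T3 C0 replicate 3). Single arrays moved more of these folds, as taken from group means. Without 2T3 low replicate 1, Ptgs2 was 122-fold and Ccl7 734-fold higher at low density. Without MLO-Y4 low replicate 2, Mag was 54.0-fold lower. Without 2T3 C0 replicate 1, Saa3 was 8424-fold higher at the denser state, and without MLO-Y4 high replicate 1 Lgals3bp was 88.7-fold higher. Pdpn was at 3.77 (SE 1.00, adjusted p = 0.0655) at low density and at 3.16 (SE 1.00, adjusted p = 0.136) at the denser state. With the replicate block Pdpn passed at both (limma adjusted p = 0.00677 and 0.0179) and Alpl at low density (0.0338). The block treats 2T3 low as paired, although its arrays did not meet the pairing rule, so the low-density passes rest on a pairing not found there. Alpl was at 3.05 and 2.65, Bglap at -2.63 and -0.60 and Ibsp at -0.97 and 0.09 (limma adjusted p from 0.174 to 1), and Phex was below the limit throughout.

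At low density 188 spots passed in limma, 162 higher and 26 lower (789 at unadjusted p under 0.05), and at the denser state 139, with 116 higher and 23 lower (695). With quantile normalization the splits were 144 to 50 and 121 to 53, and with detected-spot scaling 113 to 88 and 100 to 91. Of these calls 94 spots were shared in the same direction and 0 in opposite directions. Both come from 1 fit with a shared estimate of the spread and are not independent. The 2 sets of differences correlated across spots at r = 0.717, spots not being independent replicates. With the replicate block the counts were 308 and 236. Without 2T3 low replicate 2, 2T3 low replicate 3 or MLO-Y4 low replicate 1 the low-density count was 110, 106 and 108, and without 2T3 C0 replicate 2 or 3 the denser count was 79 and 81. Camera called 10 and 12 lists. With an estimated correlation the cytokine list held at low density (adjusted p = 0.0159), and the cytokine (0.00788), interferon (0.0282) and FGF, IGF and PDGF (0.0382) lists held at the denser state.

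The osteoblast density comparison asked what confluency changes in 2T3. No single gene passed with the settings of the report: limma called 0 of 5030 spots, and 141 had an unadjusted p under 0.05 where 251.5 are expected by chance, with 211 in the fit with the replicate block, which also called 0. The smallest p-values for higher values in C0 were those of Mab21l2 (log2 2.90, SE 0.61), Omd, an extracellular matrix proteoglycan of bone (2.40, SE 0.56), and the homeobox gene Barx1 (2.24, SE 0.56). For lower values they were those of the sphingosine phosphate receptor gene S1pr3 (-2.67, SE 0.55), the calcium-binding gene Casq1 (-2.88, SE 0.69) and the acetylcholine receptor gene Chrnb1 (-1.58, SE 0.46), all with adjusted p = 1. Pdpn was at 0.17 (SE 1.00), Alpl at 0.22 (SE 1.08), Ibsp at -0.95 (SE 0.96) and Bglap at -0.73 (SE 1.47). With array weights limma called 2 spots and 565 had an unadjusted p under 0.05. With the floor at the median it called 2, with 135 at an unadjusted p under 0.05.

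Actin cytoskeleton and contractile genes moved down as a list in C0 (median -0.61, or -0.52 with members at their bound; 24 of 25 members lower; 0 past the threshold, also adjusted over the list alone; camera adjusted p = 3.38e-04, and adjusted p = 0.949 with an estimated correlation). Members with the smallest p were Actb (-1.99, SE 0.65, and -1.84 as the mean of its spots), the calponin gene Cnn1 (-2.21, SE 0.78), Tagln (-1.48, SE 0.59) and Myl6 (-1.64, SE 0.73). The fall of Actb rested on 2T3 low replicates 2 and 3, at log2 means of 14.24 and 13.58. Low replicate 1, at 11.31, lay within the 10.90 to 11.49 of 2T3 C0. Skeletal muscle markers had a median of -0.47 with 8 of 10 lower, and camera did not call them (adjusted p = 0.266). Ribosomal protein genes moved down too (median -0.54; 25 of 29 lower; 0 past the threshold; camera adjusted p = 0.00500, and adjusted p = 0.949 with an estimated correlation), with Rps3 at -1.49 (SE 0.73) and Rpsa at -1.52 (SE 0.84). Both calls ended without 2T3 C0 replicate 3 (adjusted p = 0.0808 and 0.461), without 2T3 low replicate 2 (0.106 and 0.503) and without 2T3 low replicate 3 (0.101 and 0.163). The actin medians in these fits were -0.27, -0.61 and -0.60 and the ribosomal medians -0.13, -0.35 and -0.57, and without 2T3 low replicate 1 or 2T3 C0 replicate 1 the ribosomal medians were -1.02 and -0.99. Without the 4 arrays numbered 1 the actin and ribosomal medians were -1.15 and -1.40 (camera adjusted p = 5.7e-11 and 4.15e-15). That fit leaves out 2T3 low replicate 1, and its p-values use the preset correlation. Ribosomal protein genes had a similar median in MLO-Y4 high against low, -0.43 with 26 of 29 lower, where camera did not call them (adjusted p = 0.298). Camera did call them there with quantile normalization (adjusted p = 0.0130) and with detected-spot scaling (0.0332). 2T3 low replicate 3 was the dimmest array, with a median intensity of 4.

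The osteocyte comparison, high against low MLO-Y4, addressed cells with and without gap junctions. Interferon and antigen-presentation genes moved up as a list in MLO-Y4 high: the median was 1.05 (1.01 with members at their bound) against -0.07 for other genes, 21 of 23 members were higher, and camera gave adjusted p = 2.92e-10. With an estimated correlation the call was lost (adjusted p = 0.144), as it was when that correlation came from the fit with the replicate block (adjusted p = 0.0958), and fry gave 0.567. Fry was run without the block and so ignores the pairing of these arrays by number. The same holds for the SEs and counts of members given next. Ifit3 was at 1.97 (SE 0.66), Irf7 at 1.74 (SE 0.79), the immunoproteasome gene Psmb9 at 1.32 (SE 0.63) and Gbp2 at 0.86 (SE 0.41), and 0 members passed the threshold on their own or adjusted over the list alone. By same-numbered arrays, 17, 20 and 19 of the 23 genes were higher in MLO-Y4 high, with median differences of 1.21, 1.14 and 1.14.

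**Figure D3:**
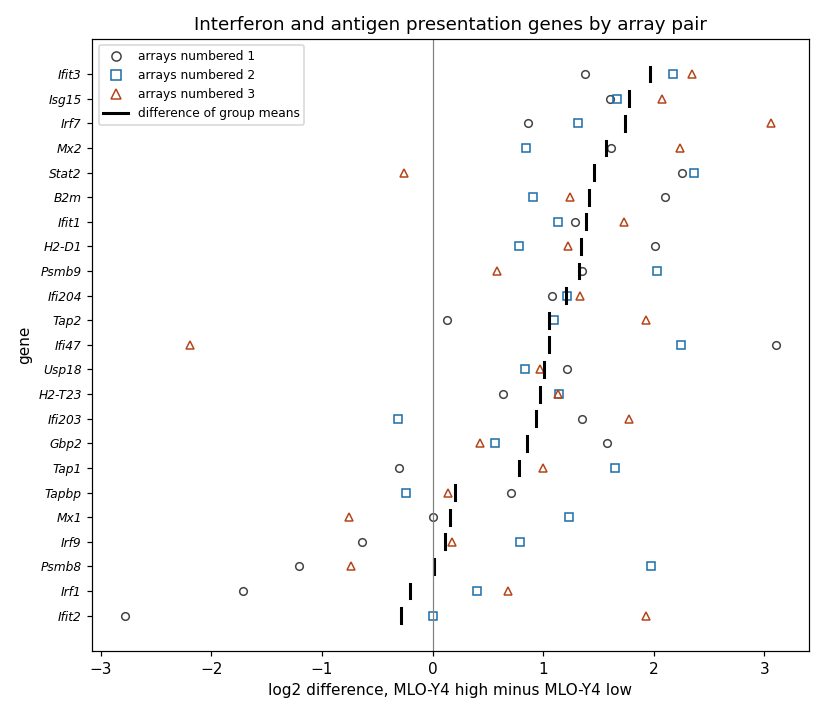
Log2 difference between MLO-Y4 high and MLO-Y4 low (horizontal axis) for each of 23 interferon and antigen-presentation genes, with a symbol for each pair of same-numbered arrays and a bar at the difference of the group means. The bars of 21 of 23 genes lie above 0, from 1.97 for Ifit3 to -0.28 for Ifit2.

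Limma called 0 of 5030 spots between the MLO-Y4 densities, with 116 at an unadjusted p under 0.05 where 251.5 are expected by chance, and 0 with the replicate block (158 unadjusted). Spots with the smallest p were Kcnab3, at least 1.42-fold higher in MLO-Y4 high, the Ras-related gene Mras, at least 1.69-fold, and the sphingomyelinase gene Smpd2, at least 1.24-fold. Lower were the RNA polymerase subunit gene Polr1c (log2 -3.24, SE 0.65), the amino acid sensing kinase gene Eif2ak4 (-2.48, SE 0.62) and Irf8, at least 1.22-fold lower, all with adjusted p = 1. Of the gap junction list, the junction scaffold gene Tjp1 was at 0.05 (SE 1.10), and the connexin genes Gja3 and Gjb6, above the limit on few arrays, at 0.40 (SE 0.49) and -0.16 (SE 0.85). Between the lines the same 3 were at 1.14, -0.23 and 0.14 (adjusted p = 0.466, 0.789 and 0.939). Pdpn was at -0.44 (SE 1.00), Alpl at -0.18 (SE 1.08), Bglap at 1.31 (SE 1.47) and Ibsp at 0.11 (SE 0.96) between the MLO-Y4 densities.

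The difference between the density effects of the lines was tested directly. Limma called 0 spots (104 at an unadjusted p under 0.05, 0 and 150 with the replicate block). Over spots above the limit on all arrays the 2 density effects correlated across spots at r = 0.144, and 53.4% had the same sign. Camera called 3 of 28 lists. The interferon and actin lists were higher and the cell cycle list lower in MLO-Y4 relative to 2T3. None held with an estimated correlation (adjusted p = 0.862, 0.986 and 0.986). With the replicate block 1 of the 3, the interferon list, was called. Pdpn was at -0.62 (SE 1.41), Alpl at -0.40 (SE 1.53), Ibsp at 1.06 (SE 1.35) and Bglap at 2.03 (SE 2.08), each with limma adjusted p = 1.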

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

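Of the tests in this part, the correlation estimated with the replicate block and the fits without the 4 arrays numbered 1 and with the surface trend removed were chosen after the data were seen.

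The gene lists of this paragraph are given here because the test of the difference between the lines' density effects called them. Actin cytoskeleton and contractile genes differed by a median of 0.53 on the log2 scale (MLO-Y4 minus 2T3; camera adjusted p = 0.0435, and adjusted p = 0.986 with an estimated correlation), from -0.61 in 2T3 and -0.29 in MLO-Y4. Cell cycle and DNA replication genes differed by a median of -0.64 (camera adjusted p = 0.0435, and adjusted p = 0.986 with an estimated correlation), from 0.25 in 2T3 and -0.32 in MLO-Y4. Both calls ended with the replicate block (adjusted p = 0.0687 each) and, of the 12 fits without 1 array, the actin call ended in 7 and the cell cycle call in 6, with medians from 0.13 to 0.97 and from -1.11 to -0.21. Without the 4 arrays numbered 1 the cell cycle median was -0.068 (adjusted p = 0.925). Interferon and antigen-presentation genes differed by a median of 1.01 (camera adjusted p = 2.78e-04, and adjusted p = 0.862 with an estimated correlation), from 0 in 2T3 and 1.05 in MLO-Y4, and the call ended with the floor at the lowest positive value (adjusted p = 0.0808). It held in all 12 fits without 1 array, with a lowest median of 0.61 without MLO-Y4 high replicate 1.

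The higher interferon genes in MLO-Y4 high than in MLO-Y4 low were set against 3 technical explanations. The list's median of 1.05 lay at percentile 100 of 10000 random lists of 23 genes matched on mean level (-0.40 to 0.17 for the central 95%), so brightness does not account for it. With a smooth trend over the array surface removed it was 1.20, which argues against a trend over the layout assumed from the spot names. A trend over another layout was not tested. Without replicate numbers 1, 2 or 3 the median was 1.05, 1.00 and 1.07, which argues against a single pair of arrays. Cell density or gap junctions, as the design names them, may underlie it, but this is a hypothesis: members of the list vary together between arrays, and with an estimated correlation the adjusted p was 0.144. That test ignores the pairing of the arrays by number, and with the replicate block it gave 0.0958. The origin of the 3 arrays per group, and so whether they are separate cultures, stays open.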

How the results depend on the processing

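Detected-spot scaling, with and without the block, the correlation estimated with the block, upper-quartile scaling, the floor at the median, the removal of the surface trend and the fit without the 4 arrays numbered 1 were chosen after the data were seen. No spot called with the settings of the report had the opposite direction under another setting that tests single spots. Of the values of the genes with the largest changes and the always-named genes under other settings, 1265 kept direction and side of the threshold, 19 lost and 2 gained a call and 27 changed sign. Of those of called lists, 389 were kept, 103 lost the call and 1 had camera's direction turned without a call. Both tallies include centring on the median log2 value, which called the same spots as the settings of the report. Genes that had no call and gained none count as kept where the sign stayed, so the tallies overstate how well calls hold. Of 85 named genes called between the lines, list members included, 8 were lost with quantile normalization, 9 with detected-spot scaling, 15 with the floor at the lowest positive value, 13 with the surface trend removed and 18 without the 4 arrays numbered 1, among them Pdpn and Mag. Between 4 and 10 were lost in the fits without 1 array, Alpl, Hspb1, Nes and Pparg in 9 of 12, Msx2, Kif20a and Plod2 in 8 and Nasp and Nr4a1 in 7. None changed direction.

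Counts of spots for MLO-Y4 against 2T3 over both densities, at low density and at the denser state were 508, 188 and 139. They were 309, 81 and 50 with the floor at the lowest positive value and 788, 433 and 361 with array weights. Fits to only the arrays compared gave 103 and 53 in the matched comparisons. The replicate block gave 308 and 236, and with detected-spot scaling the block gave 231 at the denser state. The 2T3 density count of 0 became 2 with array weights and 2 with the floor at the median. Without each array in turn the counts ran from 356 to 514, 106 to 249 and 79 to 168, and stayed 0 for the density effects and their difference. The cause of these changes was not tested.

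List counts of 2, 1, 13, 10, 12 and 3 (2T3 density, MLO-Y4 density, lines, low, denser, difference) were 0, 0, 1, 1, 3 and 0 with an estimated correlation, 0, 0, 3, 1, 3 and 0 with the correlation estimated with the replicate block, and with fry 0 for 2T3 density, MLO-Y4 density and the difference. MLO-Y4 density gave 2 with quantile normalization, 3 with detected-spot scaling with or without the block, and 2 with the surface trend removed. The difference gave 0 with the floor at the lowest positive value, 1 with the block, 1 with the floor at the median and 5 without the arrays numbered 1, where 2T3 density gave 4. Without each array in turn they ran from 0 to 3, 1 to 3, 11 to 13, 8 to 11, 8 to 14 and 1 to 3, with 1 for the difference without MLO-Y4 high replicate 2, and 3 for MLO-Y4 density without MLO-Y4 low or high replicate 1. The cause was not tested.

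Values that changed sign belonged to genes that did not pass in the comparison concerned. The cell cycle list of the difference kept a negative median, -0.068 without the arrays numbered 1, while camera's direction turned (adjusted p = 0.925). With the surface trend removed the BMP and TGF-beta median between the lines was -0.18 and the heat shock median -0.022. Phex was above the limit on 0 of 12 arrays, so its values are differences between background readings. In 2T3 density Phex was -0.17 with detected-spot scaling (also with the block) and -0.019 with upper-quartile scaling, and without the arrays numbered 1 Pdpn was -0.21 and Bglap 0.020. In MLO-Y4 density Ibsp was -0.63 with the floor at the lowest positive value, Phex -0.11 without the arrays numbered 1 and Alpl 0.021 with the surface trend removed. Between the lines Phex was -0.12 with detected-spot scaling (also with the block) and -0.72 with the surface trend removed. Without each array in turn, 2T3 density ran from -0.26 to 0.78 for Pdpn, -0.24 to 0.42 for Phex, -0.61 to 1.21 for Alpl and -1.21 to 0.084 for Bglap. MLO-Y4 density ran from -1.32 to 0.58 for Pdpn, -0.027 to 1.45 for Phex, -1.08 to 0.51 for Alpl, -0.73 to 0.79 for Ibsp and -0.22 to 2.64 for Bglap, and Phex between the lines from -0.25 to 0.49. The cause was not tested. Signal over background limits the low genes: 281 of 5030 spots were above the limit on no array.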

Other observations

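The tests of macrophage markers and of scaling were chosen after the results were seen, as was the naming of Marcks, Map1b, Actg1, Capg and Acta2.

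Several lists that camera did not call between the lines held called genes. The urokinase gene Plau (log2 4.70, SE 0.98), its receptor Plaur (3.89, SE 0.71), the tissue plasminogen activator Plat (2.82, SE 0.42) and the lysosomal protease Ctsd (2.15, SE 0.47) were the 4 of 20 matrix proteases and inhibitors that rose in MLO-Y4, and 0 fell (6 and 1 adjusted over the list alone; median 0.33, camera adjusted p = 0.237). Of 24 collagen and matrix genes 4 rose and 0 fell (the same adjusted over the list alone; median 0.38, camera adjusted p = 0.305), the thrombospondins Thbs1 (4.13, SE 0.53) and Thbs2 (4.07, SE 0.64), Col5a2 (2.58, SE 0.61) and the lysyl hydroxylase Plod2 (2.71, SE 0.72). Calls of Col5a2 and Plod2 ended with quantile normalization (adjusted p = 0.121 and 0.0628) and detected-spot scaling (0.0810 and 0.0939), and Plod2 was lost in 8 of 12 fits without 1 array. Actin genes parted, with Dstn, Zyx, Capg (2.37) and Actg1 (2.19) higher and Tmsb4x, Fscn1 and Acta2 (-2.04) lower, 4 and 3 of 25 (the same adjusted over the list alone; median 0.52, camera adjusted p = 0.773). Neurite and dendrite genes parted too, 4 higher and 2 lower of 23 (5 and 2 adjusted over the list alone; median -0.04, camera adjusted p = 0.940): the ephrin receptor Epha2 (3.58, SE 0.59), the tau gene Mapt (at least 3.12-fold), Marcksl1 (at least 5.40-fold) and Nes (1.46, SE 0.38) rose, and Marcks (-3.16) and Map1b (-2.11) fell. The call of Nes ended with quantile normalization (adjusted p = 0.418), detected-spot scaling (0.474) and in 9 of 12 fits without 1 array.

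Desaturase genes of lipid synthesis went opposite ways: Scd1 rose (log2 2.44, SE 0.43, adjusted p = 0.00443) and Scd2 fell (-3.12, SE 0.57, adjusted p = 0.00513), with the sterol reductase Dhcr7 higher (1.97, SE 0.42; adjusted p = 0.0663 with detected-spot scaling), so 2 of 7 rose and 1 fell (the same adjusted over the list alone; median 1.07, limma camera adjusted p = 0.284). Immediate early genes rose in 3 of 17 cases and fell in 0 (3 and 0 adjusted over the list alone; median 0.40, or 0.15 with members at their bound, camera adjusted p = 0.683). They were Fosl1 (2.84, SE 0.42), Myc (2.02, SE 0.36) and Nr4a1 (2.07, SE 0.54), and Nr4a1 did not pass with quantile normalization (adjusted p = 0.184) or detected-spot scaling (0.113) or in 7 of 12 fits without 1 array. Chondrocyte markers had Col10a1 (3.37, SE 0.63) and Sox5 (at least 6.90-fold) higher, 2 of 12 (median -0.25, camera adjusted p = 0.838), fibroblast markers Fbln1 (4.48, SE 0.62), 1 of 7 (median -0.17, camera adjusted p = 0.940), and endothelial markers Eng, 1 of 11 (median -0.22, camera adjusted p = 0.852), with 0 lower in each and the same counts adjusted over the list alone. The neural cadherin gene Cdh2 (-2.57, SE 0.50) was the 1 of 12 junction genes that fell, with 0 higher (median -0.11, camera adjusted p = 0.331). Muscle (10 genes, median 0.11, camera adjusted p = 0.701), mitochondrial (13, 0.47, 0.484) and ribosomal protein genes (29, 0.32, 0.852) had 0 called, while with quantile normalization the ribosomal list was lower in MLO-Y4 (adjusted p = 1.39e-04). With members at their bound, the medians of the neurite, chondrocyte, fibroblast, endothelial and junction lists were 0. Medians of the protease, collagen, actin, immediate early, mitochondrial, muscle and ribosomal lists were below 0 with detected-spot scaling.

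Cytokine, chemokine and interferon genes were higher in MLO-Y4 than in 2T3, 24 of 42 members of the 2 lists. Macrophages in the cultures are argued against by 0 of 14 macrophage and osteoclast markers higher, with Ptprc above the limit on 0 of 12 arrays and Cd68 at a log2 mean of 3.42 in MLO-Y4 low, 5.08 in MLO-Y4 high, 4.69 in 2T3 low and 4.53 in 2T3 C0. The scaling of the arrays is argued against too, since 18 of the 24 stayed called with detected-spot scaling and 22 with quantile normalization. Spill-over from bright neighbouring spots cannot be told apart: 37 neighbours, by an assumed layout of the spot names, lay 0.33 above all spots (bootstrap interval -0.061 to 0.857), against a median of 4.80 for the called members. A difference between the osteocyte and osteoblast lines, as the design names it, stays open as a hypothesis.

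Arrays with the same replicate number deviated together in MLO-Y4, with a mean correlation of 0.688 across spots. It was 0.662 with a smooth trend over the array surface removed and 0.701 with a trend in brightness removed. Neither brightness nor a trend over the layout assumed from the spot names therefore accounts for it. Replicate triplets of control spots ranged over a median of 0.902 log2 on all arrays and 2.00 and 1.91 on MLO-Y4 low and high replicate 3, where the surface trend held 16.1% and 18.6% of the deviations. A shared day or culture per number may underlie the pattern, given that 0.662, but no label states one and no biological explanation was tested.

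Other splits of the same arrays were fitted with limma. For MLO-Y4 against 2T3 over both densities, 1 of 100 splits, the real one, gave as many spots (508, with 25 for the highest other). Every other split put arrays of both lines on each side. The splits also took the arrays as exchangeable, although same-numbered arrays deviated together. The share therefore does not exclude chance. The difference between density effects called 0 spots, with 1 for the highest other split. Any split gives at least 0, so the 100 of 100 that did carry no information, and chance is not excluded. The remaining 4 comparisons have 10 splits each, too few for a share under 0.05: the real and highest other counts were 188 and 0 at low density (1 split as large), 139 and 0 at the denser state (1 split), 0 and 0 for 2T3 density (10 splits) and 0 and 1 for MLO-Y4 density (10 splits).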
